A study of Drosophila melanogaster with 4 samples.

How the data were processed

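Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map RPD3 in nuclei from heads of adult Drosophila melanogaster of the wild-type Oregon-R strain. RPD3 is the fly counterpart of the mammalian class I histone deacetylase HDAC1, a catalytic subunit of corepressor complexes. Per the labels' protocols, flies came from population cages kept on a 22-day adult cycle, heads were separated with sieves, tissue was fixed with formaldehyde, and chromatin was sheared by sonication before immunoprecipitation on protein A beads. The series holds 4 samples, namely 2 RPD3 ChIP samples and 2 inputs, each input paired with 1 ChIP sample per the labels. The labels call them replicates 1 and 2 and do not say whether these came from separate fly populations, so any spread between them may be technical.

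Bowtie 0.12.7 is named in the submitters' processing notes. The cluster caller, its threshold and the depth of each library are not given in the sources used here, and inputs and read counts were not analysed here. The deposited files are lists of enriched clusters, 1 list per ChIP sample and 1 combined list for the replicate set. How the combined list was made (pooled reads or another way) is not given in the sources used here, so it was treated as the authors' own summary and never as another replicate. Per the file headers, positions are on FlyBase release 5 of the genome, and they are given here 1-based. Each cluster in the deposited lists carries the authors' score, which was read as a log2 enrichment of ChIP over input. The headers do not name this scale. It was inferred from the values: raised as powers of 2, the 5 highest distinct scores of the combined list were 9, 10, 11, 12 and 13 times the same step, each within 4.1e-09 of a whole number. The scaling factor between ChIP and input is not given, so score levels were not compared between lists. Scores were used to describe, rank and filter clusters within a list, to test gaps within a list, and to correlate the replicates, which does not depend on a constant offset between them. The combined list also holds 1 region named as depleted (3L, 12734232 to 12735926, score -0.04), which was left out.

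The gene table supplied for names is of release 6 of the genome and the clusters are on release 5. Coordinates were not converted between releases, so clusters were not assigned to genes, and the planned tests of transcription start sites, gene lists and sequence motifs were not run. Clusters are therefore named by position. By a rule fixed before the data were examined, the text names the 10 highest-scoring and the 5 widest clusters of the combined list among those that overlap a cluster in both replicates.

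Clusters of different lists were called shared where they overlapped by at least 1 bp. The overlap expected by placement alone was taken from 1000 circular shifts, in which all clusters of a sequence are moved by the same random offset along the length in the file header. The one-sided permutation p is the share of shifts with at least the observed overlap, and 0.000999 is the smallest value these shifts can give. Spearman's rho of scores was computed over clusters matched 1 to 1, with a two-sided permutation p from all circular rotations of 1 list against the other. The gap in median score between the X and the autosomal arms was tested within each list by all circular rotations of the scores along the clusters in genome order, two-sided. The share of clusters on each sequence was compared between the replicates by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 13 sequences. This test compares the 2 lists, not conditions, and treats them as independent although most of their clusters are shared. The tests of the X score gap and of these shares were not in the plan fixed beforehand. Their p-values do not allow for that choice. Shares of clusters carry 95% exact (Clopper-Pearson) intervals, which cover counting error over clusters only. Clusters are not independent replicates. All tests run over clusters, within a list or between the 2 lists, and none compares groups of samples. The number of reads behind a cluster is unknown.

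The functions were tested on simulated data. With 59.3% of replicate 1 clusters planted in a second list, 59.9% were found shared over the 5550 clusters. Of 40 unrelated lists, each a circular shift of replicate 1 itself, 2.5% gave p under 0.05. These lists were made as the shifts of the test are, so this checks the function and not other unrelated lists. A planted X gap of 0.2 was recovered as 0.22. Scores were permuted over clusters beforehand, so this check held no likeness between neighbouring scores. Alternatives were a stricter overlap (at least 50% of the shorter cluster), the better-scoring 50% of each list, lists of equal length, joining of clusters under 500 bp apart, covered length in place of cluster number, the combined list in place of the replicates, and each replicate alone. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.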

Results

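The series asked where RPD3, a histone deacetylase, occupies the genome of adult Drosophila heads. RPD3 was immunoprecipitated from head nuclei in 2 replicate samples, each with its own input, which the labels tie to that sample's cluster list. The replicate 1 list held 5550 enriched clusters covering 17.7 Mb, and the replicate 2 list held 5872 clusters covering 17.4 Mb. On the 5 large arms, X, 2L, 2R, 3L and 3R, clusters took up 14.6% of the sequence in replicate 1 and 14.4% in replicate 2. These arms carried 97.5% of the clusters of replicate 1 and 98.2% of those of replicate 2. The median cluster was 2609 bp wide in replicate 1 and 2511 bp wide in replicate 2, and the narrowest were 1301 and 1302 bp. Read depth per library is unknown.

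The first question was how RPD3 clusters were distributed over the chromosomes. Clusters were spread over all large arms at similar densities and were sparse in assembled heterochromatin. The highest density was on 2R, with 54.7 ± 2.14 clusters per Mb (SD, n = 2), followed by 3R with 47.9 ± 3.09, X with 44.7 ± 0.284, 3L with 44.4 ± 2.39 and 2L with 43.6 ± 2.34. The density of 2R was 1.2 ± 0.023 times that of the other autosomal arms, and it was the highest of the large arms in each replicate. Within each replicate, 3R exceeded 3L (by 2.99 and 3.98 clusters per Mb), 2L (by 3.76 and 4.82) and X (by 1.18 and 5.15). The X exceeded 3L and 2L in replicate 1 and not in replicate 2, where the differences were -1.17 and -0.329. The differences between arms were not tested across the 2 samples, and these values are descriptive.

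The heterochromatic scaffolds, which are the assembled repeat-rich pieces near centromeres and of the Y chromosome, held few clusters. The 6 scaffolds together carried 36 clusters in replicate 1 and 30 in replicate 2, or 3.56 ± 0.457 clusters per Mb (SD, n = 2). This was 0.075 ± 0.014 times the density of the autosomal arms. The ratio was 0.118 in the combined list and 0.0481 both in the better-scoring 50% of each list and among clusters wider than the list median. Among them the X scaffold (XHet) had 4 clusters in each replicate, the Y scaffold (YHet) had 1 in each, and the latter did not overlap between replicates. The pool of unplaced scaffolds, U, had 2.94 ± 0.352 clusters per Mb. How the authors treated reads from repeated sequence is not given in the sources used here.

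**Figure D1:**
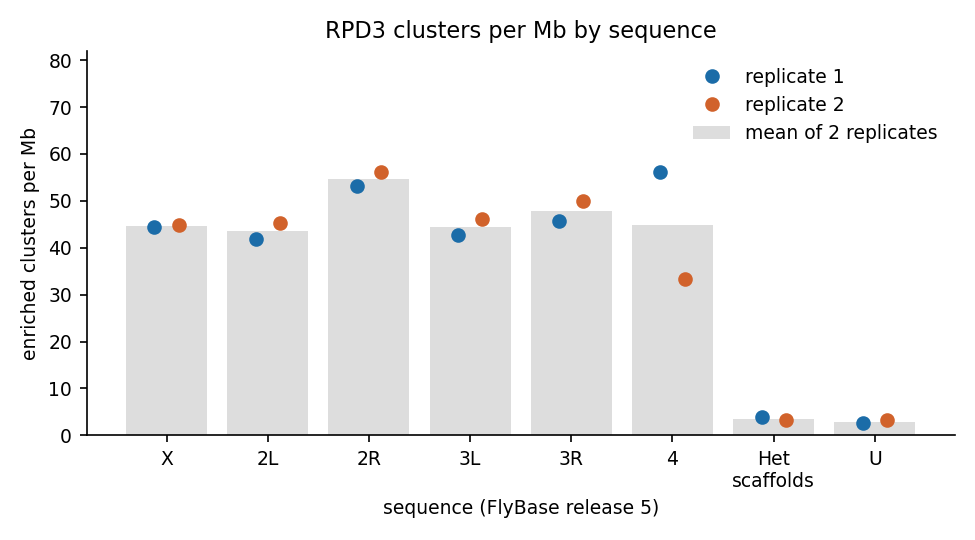
Enriched RPD3 clusters per Mb (y axis) on each large arm, chromosome 4, the 6 heterochromatic (Het) scaffolds together and the unplaced scaffolds U (x axis); points are the 2 replicates and bars their mean. Large arms lie between 41.9 and 56.2 clusters per Mb, the Het scaffolds and U lie under 4, and chromosome 4 differs between replicates.

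Chromosome 4, the small and largely heterochromatic autosome, was the sequence on which the replicates disagreed. It carried 76 clusters (56.2 per Mb) in replicate 1 and 45 clusters (33.3 per Mb) in replicate 2. Relative to the autosomal arms its density was 1.23 times as high in replicate 1 and 0.676 times in replicate 2, so the direction by cluster number differed between replicates. By covered length it was below the autosomal arms in both, at 0.938 and 0.616 times their covered share. Among clusters wider than the list median its density was 0.675 ± 0.066 times the autosomal one, and in the better-scoring 50% of each list it was 0.354 ± 0.07 times (SD, n = 2). Its share of all clusters was 1.37% (95% exact interval 1.08 to 1.71) in replicate 1 and 0.766% (0.56 to 1.02) in replicate 2. This was the 1 of 13 sequences whose share differed between the lists (Fisher's exact test, two-sided, p = 0.0018, Benjamini-Hochberg adjusted p = 0.023). The chromosome 4 clusters were low in score in both lists, with medians of 0.52 and 0.59 against 0.75 and 0.84 on the autosomal arms. In the better-scoring 50% of each list, chromosome 4 had 9 clusters in replicate 1 and 13 in replicate 2, and the lists did not differ past the threshold there (ratio of shares 1.37, Fisher's exact p = 0.53).

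The X chromosome did not carry more clusters than the autosomes, but its clusters had higher scores. Clusters per Mb on the X were 0.943 ± 0.044 times those on the autosomal arms (SD, n = 2). The median score of X clusters was 0.93 against 0.75 for autosomal-arm clusters in replicate 1, a gap of 0.17 (two-sided permutation p = 0.0015 over rotations). In replicate 2 it was 0.97 against 0.84, a gap of 0.14 (permutation p = 0.017). These p-values concern the placement of the X block along the clusters, and not how unusual the X is among the large arms. The mean gap was 0.15 ± 0.03 on the log2 scale (SD, n = 2). The X median exceeded that of each of the 4 autosomal arms in both replicates, the highest autosomal median being that of 3R at 0.80 in replicate 1 and 0.85 in replicate 2. Restricting each list to its better-scoring 50% turned the X density from 0.943 to 1.19 times the autosomal one, a shift that follows from selecting on a score that was higher on the X. Within that part the score gap, which a common cutoff can narrow, was 0.08 in replicate 1 (permutation p = 0.027). In replicate 2 it was 0.04 and did not pass (permutation p = 0.077).

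The second question was how far the 2 replicates found the same sites. Of the 5550 clusters of replicate 1, 4655 overlapped a cluster of replicate 2, or 83.9% (95% exact interval 82.9 to 84.8). Of the 5872 clusters of replicate 2, 4828 overlapped replicate 1, or 82.2% (81.2 to 83.2). Circular shifts of the other list gave 26.4% ± 0.878 (SD over 1000 shifts) and 25% ± 0.826, and no shift reached the observed share (one-sided permutation p = 0.000999 for each, the smallest possible). By length, 13.6 Mb were covered in both replicates, which was 63.3% of the 21.5 Mb covered in either. Excluding chromosome 4 and the scaffolds left the shares at 84.4% and 82.3%.

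Clusters that recurred were wider and higher in score than those that did not. Width and score rose together within each list (Spearman's rho 0.738 in replicate 1 and 0.770 in replicate 2), so these differences are not independent of each other. In replicate 1 the median width was 2834 bp for shared and 1748 bp for unshared clusters, and the median score was 0.87 against 0.54. In replicate 2 the widths were 2732 and 1887 bp and the scores 0.97 and 0.51. Among the 10% of clusters with the highest scores, 98.6% of replicate 1 clusters (95% exact interval 97.2 to 99.4) and 99.8% of replicate 2 clusters (99.1 to 100) recurred. Among the 10% with the lowest scores the shares were 68.1% (64.1 to 72) and 53.2% (49.1 to 57.3). The rise was not steady in replicate 1, where the next 2 groups of 10% had lower shares, 60.2% (56 to 64.3) and 63.4% (59.3 to 67.4). All 67 clusters of 10 kb or wider in replicate 1 and all 34 in replicate 2 overlapped the other list. A wider cluster meets the 1 bp rule more often by placement alone. No shifts were run by width, so these shares have no baseline. On chromosome 4, 40 of 76 replicate 1 clusters recurred, or 52.6% (40.8 to 64.2), while 39 of 45 replicate 2 clusters did, or 86.7% (73.2 to 94.9).

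**Figure D2:**
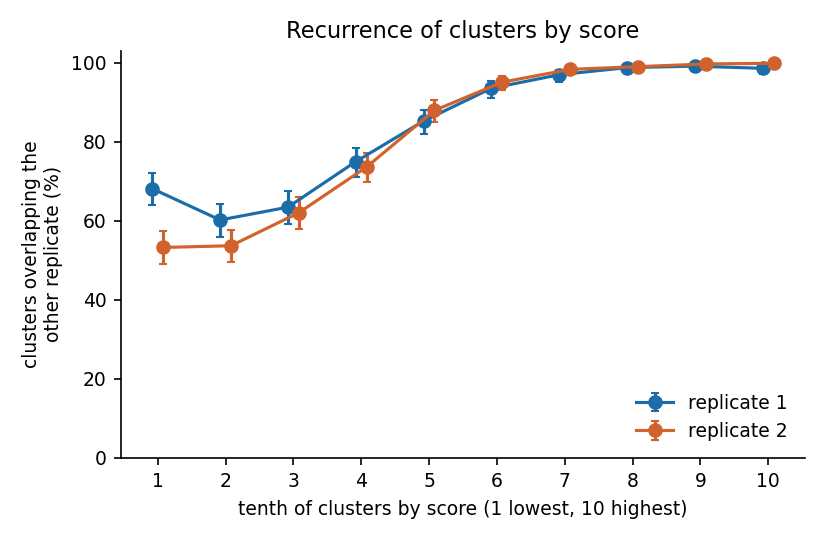
Share of clusters that overlap a cluster of the other replicate (y axis, percent) in 10 equal groups by cluster score within each list (x axis); bars are 95% exact intervals. The share is 98.6% and 99.8% in the highest group and 68.1% and 53.2% in the lowest; in replicate 1 the lowest share, 60.2%, is in the second group.

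The authors' scores ranked sites similarly in both replicates. Over 3946 clusters matched 1 to 1, Spearman's rho was 0.667 (two-sided permutation p = 0.00025 over rotations, the smallest possible) and Pearson's r was 0.687. These are correlations across clusters, which are not independent replicates. The 394 highest-scoring pairs by replicate 1 and the 394 by replicate 2 had 194 in common, where 39.3 would be shared by unrelated rankings. Cluster widths gave a rho of 0.646 over the same pairs.

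**Figure D3:**
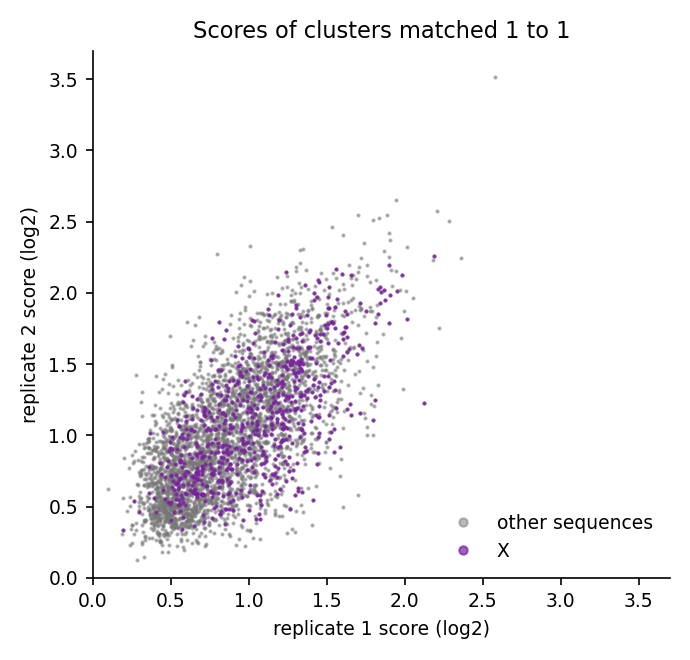
Authors' log2 score of each cluster matched 1 to 1, in replicate 1 (x axis) and replicate 2 (y axis), with X clusters in purple and all others in grey; 1 point is 1 of 3946 pairs. The scores rise together (rho 0.667), and the highest pair lies at 2.58 and 3.52.

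The third question was which sites stood out in the authors' combined list. It held 7386 enriched clusters covering 22.3 Mb. Of these, 4503 overlapped clusters in both replicates, or 61% (95% exact interval 59.8 to 62.1). A further 705 overlapped replicate 1 alone, 1005 overlapped replicate 2 alone, and 1173, or 15.9% (15.1 to 16.7), overlapped neither. Clusters found in both replicates had a median width of 3261 bp and a median score of 0.87. Those found in neither had a median width of 1167 bp and a median score of 0.37. Among the better-scoring 50% of the combined list, 95.2% overlapped both replicates. Of the replicates' own clusters, 94.8% of replicate 1 and 99.4% of replicate 2 had a counterpart in the combined list.

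The highest-scoring site found in both replicates lay on 2L from 12519262 to 12522238 (2977 bp), with a combined score of 2.93. It ranked second in replicate 1 (score 2.58) and first in replicate 2 (score 3.52). The next lay on 3L from 14666132 to 14668556, with a score of 2.44, and ranked 6 in replicate 1 and 3 in replicate 2. Both arms of chromosome 3 contributed more of the top sites. On 3R these were 3633838 to 3637566 (score 2.31) and 22012872 to 22015732 (score 2.27), and on 3L it was 22126548 to 22131078 (score 2.22). On chromosome 2 the remaining top sites were 2R from 6992650 to 6996566 (score 2.19), 2L from 19507046 to 19510010 (score 2.19) and 2L from 601304 to 603914 (score 2.16). The unplaced scaffolds U held a pair of the 10 sites, at 9710012 to 9712814 (score 2.35) and 9094062 to 9096780 (score 2.29). All 10 ranked within the first 94 clusters of replicate 1 and the first 27 of replicate 2. They were chosen by score in the authors' summary of these replicates, so high ranks there are no separate support. No X cluster was among the 10.

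The widest sites of the combined list lay on 2L and 3R, and most did not have 1 common extent in both replicates. They scored above the combined-list median of 0.59 and below the 10 highest-scoring sites. The widest covered 26657 bp of 2L, from 11986602 to 12013258, with a score of 1.26. The others lay on 3R from 5902446 to 5927310 (24865 bp, score 1.09), 3R from 4863740 to 4884392 (20653 bp, score 1.16), 3R from 11185886 to 11206160 (20275 bp, score 0.85) and 2L from 4964968 to 4984032 (19065 bp, score 1.09). The second had nearly the same extent in both replicates, from 5904906 to 5927360 in replicate 1 and from 5902405 to 5927163 in replicate 2. For the fourth, the replicate 1 cluster with the largest overlap ran from 11185665 to 11194740 and the replicate 2 cluster from 11194725 to 11206156. These met only at their ends. For the first, such clusters ran from 11986306 to 12008730 in replicate 1 and from 11998116 to 12013248 in replicate 2. For the third they began at 4863844 and 4871396, and for the fifth they ended at 4982945 and 4975216. Genes at these positions are not given, because an annotation of release 5 was not used here.

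**Figure D4:**
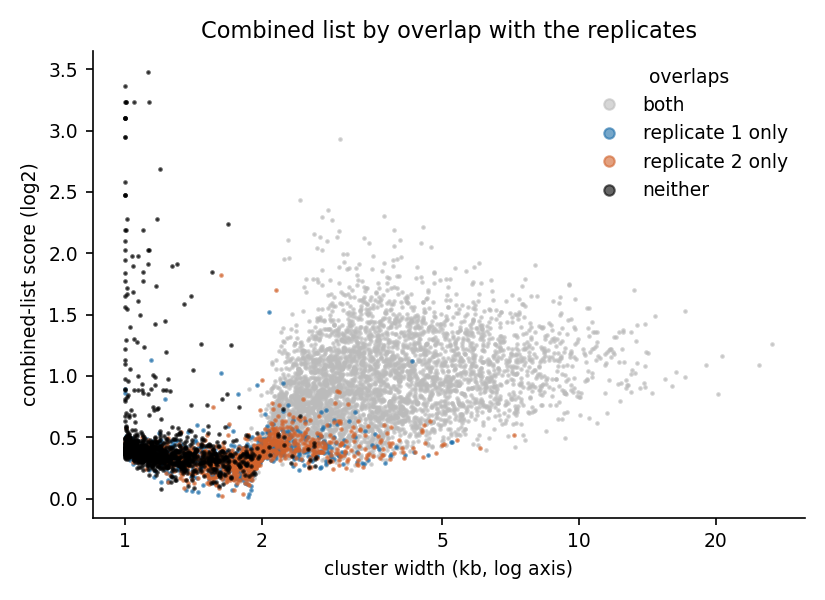
Width (x axis, kb, log axis) and authors' log2 score (y axis) of the 7386 clusters of the combined list, coloured by whether they overlap a cluster in both replicates, in 1 of them or in neither. Clusters in both are wide (median 3261 bp), and those in neither are narrow (median 1167 bp), and include 18 of the 20 highest scores.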

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

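Alternatives limited to large arms, to wide clusters or to clusters at least as wide as the narrowest replicate cluster, and all those for the X score gap and the chromosome 4 shares, were chosen after seeing the data. The overlap of the replicates passed the shift test under all 5 alternatives (200 shifts each), at 80.2% to 85.4% for replicate 1 and 78.8% to 83.9% for replicate 2, and the rho of scores was 0.665 with the stricter overlap and 0.666 on the large arms, and that of widths was 0.646. The lower overlap in the better-scoring 50% (80.2% and 78.8%) follows from its construction, since a counterpart in the lower 50% no longer counts. In the better-scoring 50% of each list, density relative to the autosomal arms moved with the scores of each sequence, from 0.943 to 1.19 for the X, from 0.953 to 0.354 for chromosome 4 and from 0.0753 to 0.0481 for the heterochromatic scaffolds. Among clusters wider than the list median it was 1.01 for the X and 0.0481 for the scaffolds, whose value was 0.118 in the combined list and 0.0599 by covered bp. Each replicate alone gave 0.912 to 0.974 for the X, 0.676 to 1.23 for chromosome 4, 0.0656 to 0.0849 for the scaffolds and an X score gap of 0.14 to 0.17. The X score gap passed its test with means in place of medians and in the combined list and did not in the better-scoring 50% (mean 0.059, permutation p = 0.027 in replicate 1 and 0.077 in replicate 2). The chromosome 4 share of replicate 2 over replicate 1, 0.56, reversed to 1.37 in the better-scoring 50% and was 0.902 among clusters wider than the list median (Fisher's exact p = 0.53 and 0.76). The lower-scoring 50% held 67 of the 76 chromosome 4 clusters of replicate 1 and 32 of the 45 of replicate 2. The combined list's share overlapping both replicates rose from 61% to 95.2% in its better-scoring 50% and to 70.9% without clusters narrower than 1301 bp. Why these values moved was not tested beyond this. Alternatives fixed beforehand for start sites, gene lists and motifs were not run, since those results need an annotation of release 5. No paired analysis was possible because the inputs have no values of their own here and the 2 ChIP samples form 1 group. Without read counts, what depth limits cannot be stated.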

Other observations

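The tests of centromere-proximal density, of a calling threshold and a rescaling on the X, of replicate 2 list length and of tied scores were chosen after the data were seen. RPD3 clusters were sparser near the centromere on the X, 2L, 2R and 3L in both replicates, and only the X and 3L passed the test in each. Within 2 Mb of the centromere end, the X had 23 clusters per Mb in replicate 1 against 46.6 over the rest of the arm, and 21 against 47.3 in replicate 2. On 3L the values were 11.5 against 45.5 and 12 against 49.1. The X and 3L passed a two-sided circular-shift permutation test in each replicate (adjusted p = 0.044 for each, Benjamini-Hochberg over 10 comparisons). Most clusters are shared between the lists, so passing in both is not independent support. On 2R the proximal density was 0.427 and 0.394 times that of the rest (permutation test, adjusted p = 0.044 in replicate 1 and 0.057 in replicate 2). On 2L it was 0.538 and 0.519 times that of the rest and did not pass (permutation test, adjusted p = 0.077 in each). On 3R it was 1.22 and 1.11 times that of the rest (permutation test, adjusted p = 0.3 and 0.49).

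X clusters scored higher than autosomal clusters over the whole of each list, by 0.12 at the 10th, 0.17 at the 50th and 0.13 at the 90th percentile of scores in replicate 1 and by 0.15, 0.14 and 0.13 in replicate 2. Wider clusters on the X would leave no gap at matched width, and the smaller width-matched gap was 0.12 (95% bootstrap interval 0.10 to 0.14, clusters resampled). A calling threshold acting at lower X depth stays open, since it would move every percentile of the clusters that remain, the 90th included. The gap in the better-scoring 50% of each list, 0.059 on average, does not decide it. A common cutoff can narrow gaps of other origins too. A rescaling of the whole X between ChIP and input, for example through a different sex ratio in the flies behind them, and a higher RPD3 occupancy of the X cannot be told apart either, because the lists hold no unenriched windows and the X density, at most 0.974 times the autosomal one, met neither bound set for it.

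Chromosome 4 clusters of replicate 1 recurred in replicate 2 less often than those of the large arms, at 52.6% against 84.4%. Sets of large-arm clusters matched on score and width recurred more often, at 77.5% on average (central 95% of 10000 sets 68.4 to 85.5). Of the 10000 sets, 0 was as low as chromosome 4. The share lay outside the central 95% of matched sets, the bound set beforehand. For these 76 clusters this argues against low scores and narrow widths as the whole cause. It does not show what else lowered the recurrence. With 45 chromosome 4 calls in replicate 2 against 76 in replicate 1, the number of calls itself limited the share that could recur. The replicate 2 list was not the shorter one, with 1.07 times as many clusters as replicate 1 on the large arms (95% exact interval 1.03 to 1.11). The interval treats the lists as independent, although most of their clusters are shared. The lower recurrence goes with the lower number of calls on chromosome 4 itself, 45 against 76, and 86.7% of those 45 overlapped replicate 1, against 82.3% on the large arms. The shortfall lay in the lower-scoring clusters, since the better-scoring 50% of each list had 13 calls in replicate 2 against 9 in replicate 1. Among clusters wider than the list median the ratio of shares was 0.902 (Fisher's exact p = 0.76), against 0.56 over all clusters. The shortfall thus lay mainly in clusters no wider than the list median, though these were not tested apart. Why it arose stays open. A difference between the inputs, which were not analysed here, is among the explanations left untested.

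Many of the highest scores of the combined list belonged to clusters that neither replicate contained. Of its 20 highest scores, 18 overlapped neither replicate, 14 of these lay on U or heterochromatic scaffolds, and their median width was 1001 bp. Of all 1173 such clusters, 68.4% (95% exact interval 65.6 to 71) were narrower than the narrowest replicate cluster, so a smaller minimum width in the combined list may account for most but not all of them. Exactly tied scores, as ratios of small whole numbers would give, were found in 35% of these clusters and in 3.51% of those in both replicates (odds ratio 14.8, 95% interval 12.1 to 18.2). Ties were also found in 18.9% of clusters overlapping replicate 1 alone and 17.6% of those overlapping replicate 2 alone. The median scores of these classes, 0.34 and 0.35, were near the 0.37 of clusters in neither, against 0.87 in both. Ties were thus not particular to clusters in neither, though most frequent there. Scores made from few reads could give such ties, but read counts were not analysed here. Ranking the combined list by score alone may place clusters found in neither replicate first.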
